A study of Mus musculus with 18 samples.

How the data were processed

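RNA was measured in 18 libraries of mouse optic nerve head tissue isolated by laser capture microdissection, in which chosen tissue is excised from a section under a microscope. Per the labels, 8 libraries came from B6.EDA+/+ mice and 10 from C57BL/6J controls. As background, EDA+/+ mice were engineered so that fibronectin transcripts constitutively include the extra domain A (EDA) exon, which is spliced variably in wild-type mice. At 22 months there were 3 EDA-labelled and 5 control-labelled libraries, and at 12 months 5 of each. Groups were taken from the labels, and replicates were numbered in accession order, so no library was paired with another. The labels give no sex, litter or processing batch, and do not state whether each library came from a separate animal. The number that opens each title lies in a separate range for each group, so a processing order that followed it could not be told apart from the group. The p-values therefore measure the spread between these libraries, which may be technical in part.

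Per the labels' protocols, cDNA was made from low-input total RNA with the SMART-Seq v4 kit and turned into libraries with Nextera XT, which keeps no strand information, and was sequenced in read pairs on a NovaSeq instrument. Reads were aligned with STAR and quantified with RSEM, per the labels' protocols, and the genome build GRCm39 was named per the submitters' processing notes. Tool versions and the gene annotation are not given in the sources used here. RSEM divides reads that match several genes or isoforms among them by estimated likelihood. Values of near-identical genes, of overlapping genes and of isoforms are therefore estimates.

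The deposited gene tables hold the authors' expected counts, which are estimated and need not be whole: 3.59% of the gene values were not whole, and all were rounded before any count test. The deposited isoform tables hold the authors' TPM values (transcript abundance scaled for transcript length and library total), which were used here only for the fibronectin exon share. The 55416 gene identifiers carried no symbols, and 52083 were given a symbol from the GENCODE M21 annotation of GRCm38. That annotation belongs to another build, so it served only for symbols, for the exon structure of Fn1, for transcript length and GC content, and for which genes lie near Fn1. Identifiers without a symbol stayed in the tests under their identifier and held 4.40% to 33.4% of the reads of a library.

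Library totals ran from 13097498 to 18488733 expected counts. No 2 libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom between 2 libraries of a group was 42.8.

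Genes were kept with filterByExpr, which left 15118, and scaled by TMM. A quasi-likelihood negative binomial model with a mean for each of the 4 groups was fitted in edgeR 4.0.16 with robust dispersion estimates, and 5 contrasts were tested two-sided: genotype at each age, age within each genotype, and their interaction. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Errors of log2 fold changes are standard errors from that model. Gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, two-sided. Of 51 lists of pathway and cell type marker genes, the 44 with at least 5 tested members were compared, and their p-values were adjusted over those 44. For each list the members past the threshold were also counted with p-values adjusted over the list alone. A list score is the mean over members of log2 CPM less the gene's mean over the 18 libraries. Single values per library were compared by exact two-sided permutation tests of the difference of means. Correlations across libraries used 100000 permutations of values less their group means.

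The fibronectin exon share is the TPM of the 4 Fn1 isoforms that hold the EDA exon, divided by the TPM of all 8 that hold both neighbouring exons, in percent. The exon was located in the annotation by its translated sequence. Where the share was 0, the limit that a count of 0 allows was taken as 3 reads of those that RSEM gave to the isoforms that span the exon. Only reads that reach the exon or its junctions can show it, so this limit is too low by an amount that was not measured, and it covers counting error only, since reads after amplification are not independent molecules.

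The genes named were set by rule. For each comparison up to 12 genes past the threshold in each direction were to be named, and where fewer than 5 passed, the genes with the smallest unadjusted p in that direction filled up to 5 and are given as not passing. They needed a mean of at least 2 log2 CPM, a symbol that is not a predicted model, and at least 4 of 5 or 3 of 3 libraries of a group beyond the other group's median. In addition 13 focal genes of fibronectin, its receptor and fibrosis or inflammation were named in both genotype comparisons, and up to 4 members with the smallest p of each list described. Some genes that this rule selects are not reported here. The groups, the lists, the main tests, the rule for named genes and the first set of alternative settings were chosen before the data were examined.

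That set held DESeq2 size factors, no filter or a mean of at least 2 log2 CPM, the DESeq2 1.42.0 Wald test, voom with sample quality weights, only the compared groups in the fit, covariates for the photoreceptor score, the myelin score or Xist against Y-linked genes, the first surrogate variable from sva 3.50.0, an estimated correlation within lists, expected counts or protein-coding isoforms for the exon share, and leaving out each library in turn. Chosen after seeing the data were a covariate for the share of reads on ENSMUSG00000119584, a covariate for the number of genes detected, leaving out EDA_12mo replicate 4 and EDA_22mo replicate 3 together, quality weights and the Xist covariate in the list tests, and exact tests of library measures and list scores.

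The gene and list tests were tested on simulated data drawn from the real means and library sizes with 200 genes altered singly, 50 at each of 4 folds, and 5 lists of 20 genes altered 2-fold. All altered genes had a mean of at least 2 log2 CPM, so the rates found do not cover genes of lower expression. For 3 against 5 libraries, the test found 2%, 28%, 62% and 86% of genes altered 2-fold, 4-fold, 8-fold and 16-fold among 14373 tested. For 5 against 5 libraries, it found 2%, 36%, 74% and 86% among 14320 tested. In each of these simulations 2 unaltered genes were called, all 5 altered lists were called, and 0 of 40 unaltered lists were called. Simulated genes vary independently, which real genes in a list need not do. The analysis used R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.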

Results

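The series asked whether mice with constitutive inclusion of the fibronectin EDA exon show fibrotic and inflammatory changes at the optic nerve head, where axons of retinal ganglion cells leave the eye, at 12 and 22 months of age. The EDA domain of fibronectin is known as a damage-associated ligand of Toll-like receptor 4. RNA of laser-captured optic nerve head was compared between 3 libraries labelled B6.EDA+/+ and 5 labelled C57BL/6J at 22 months, and between 5 and 5 at 12 months. The libraries held 13097498 to 18488733 expected counts, and 9703 to 13048 genes had 10 or more reads. Gfap, the intermediate filament of astrocytes, took 0.54% to 3.46% of reads.

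Composition varied between libraries of a group. ENSMUSG00000119584, a gene without a symbol in the annotation used, took 3.26% to 32.85% of reads. It has 1 transcript, of 1849 nt, and which RNA it encodes was not settled, so its share may be technical in part. Its share was 9.70% ± 6.65 (SD, n = 3) in EDA-labelled and 21.7% ± 8.82 (SD, n = 5) in control-labelled libraries at 22 months, with an exact permutation p of 0.071. At 12 months it was 11.1% ± 5.34 and 20.2% ± 8.33 (SD, n = 5 each), with an exact permutation p of 0.087. Genes encoded on the mitochondrial genome together took 1.93% ± 0.401 and 3.54% ± 0.875 of reads at 22 months, with an exact permutation p of 0.036, the smallest that 3 against 5 libraries allow, and 0.248 after adjustment over 7 library measures. Xist was abundant and Y-linked transcripts near 0 in 5 libraries, 3 of them EDA-labelled, and all 5 control-labelled libraries at 22 months carried Y-linked transcripts.

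**Figure D1:**
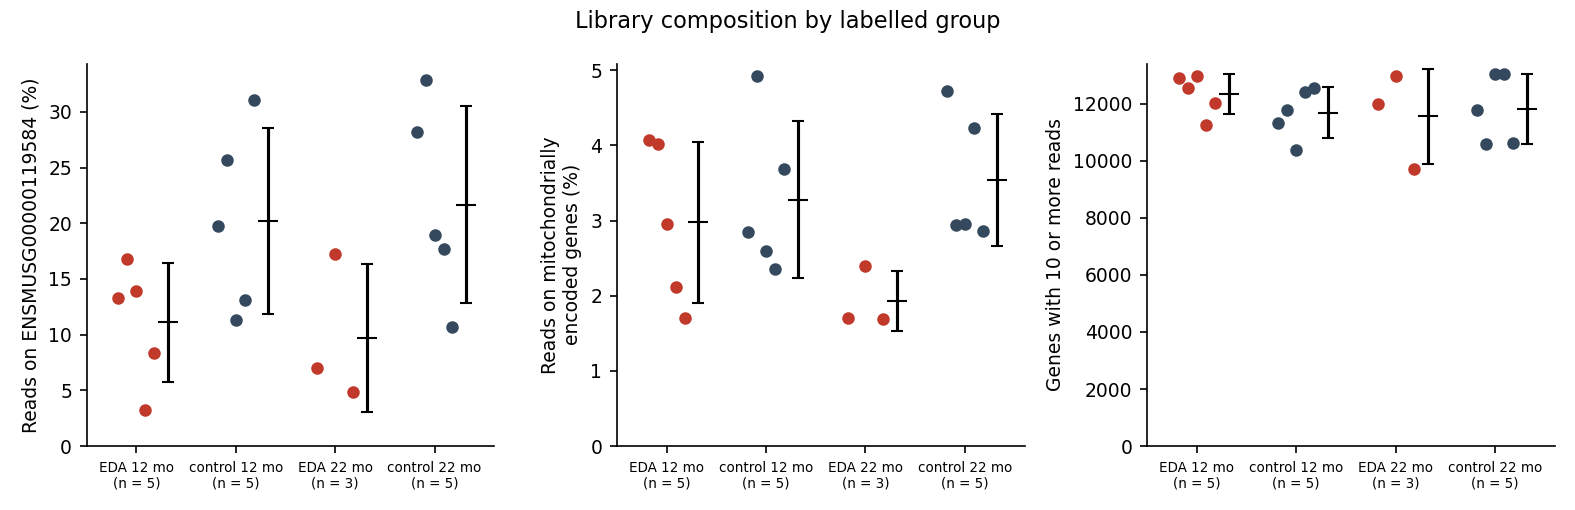
Composition of each library by labelled group. The panels show, on the vertical axes, the percent of reads on ENSMUSG00000119584, the percent of reads on mitochondrially encoded genes and the number of genes with 10 or more reads. Each dot is a library, and black marks show the group mean with SD. At 22 months the mitochondrial share was 1.93% ± 0.401 in the 3 EDA-labelled and 3.54% ± 0.875 in the 5 control-labelled libraries.

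The EDA exon itself was examined first, because it should separate the genotypes. It is exon 33 of 46 of Fn1 on the minus strand of chromosome 1, from 71603660 to 71603929 in GRCm38, and is 270 nt of coding sequence. Among Fn1 isoforms that span it, the share holding the exon was 4.2% ± 7.3 (SD, n = 3) in EDA-labelled and 41.8% ± 53.3 (SD, n = 5) in control-labelled libraries at 22 months, with an exact permutation p of 0.571. At 12 months it was 22.8% ± 28 and 31.1% ± 44.6 (SD, n = 5 each), with an exact permutation p of 0.762. The share was 0 in 4 of 8 EDA-labelled and in 5 of 10 control-labelled libraries. The highest share was 12.6% in EDA-labelled and 100% in control-labelled libraries at 22 months, and 58.5% and 96.2% at 12 months. Constitutive inclusion would instead put every EDA-labelled library near 100%. Set against the reads on isoforms that span the exon, a count of 0 allows up to 0.49% to 3.12%, but only reads that reach the exon or its junctions can show it, so the true limit is higher and was not measured. The exon thus did not follow the genotype labels in these isoform estimates, which rest on 68 to 1485 Fn1 reads per library and on RSEM's division of reads among isoforms. For that reason libraries are called EDA-labelled and control-labelled throughout, and every genotype direction below is between labels. Without WT_12mo replicate 5 the difference at 12 months turned from -8.3 to 7.9 percentage points.

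**Figure D2:**
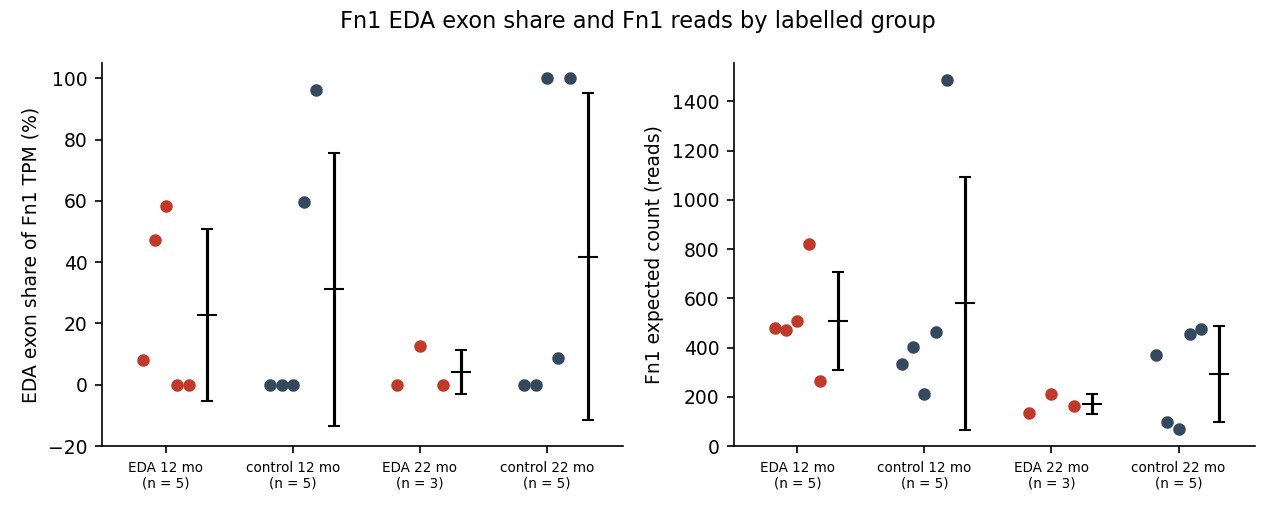
Share of Fn1 isoform abundance (percent of TPM) that holds the EDA exon, on the left, and expected counts of Fn1 reads, on the right, by labelled group. Each dot is a library, and black marks show the group mean with SD. Of the EDA-labelled libraries, 4 of 8 sit at 0, and Fn1 held 68 to 1485 reads.

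At 22 months, mitochondrially encoded transcripts were lower in EDA-labelled than in control-labelled libraries. All 12 tested members lay below 0, with a median log2 fold change of -1.02 (camera, adjusted p = 6.24e-07, and adjusted p = 0.322 with an estimated correlation). Members with the smallest p were mt-Nd4 (-1.35 ± 0.44), mt-Nd5 (-0.99 ± 0.40) and mt-Nd6 (-1.01 ± 0.44), subunits of complex I, and mt-Cytb (-1.25 ± 0.42), of complex III. Adjusted over the list alone, 2 members passed, and over all genes 0 did. The list score was -1.40 in EDA_22mo replicate 1 and -0.26 and -0.28 in replicates 2 and 3. Without replicate 1 the list was still called, with an adjusted p of 0.0212 (camera). The list of nuclear-encoded oxidative phosphorylation genes was not called, with a median of 0.06 over 59 members (camera, adjusted p = 0.386).

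Lists of matrix genes at 22 months leaned in different directions and none passed in the main test. Of 26 enzymes that build or remodel matrix, 19 were above 0, with a median of 0.27 (camera, adjusted p = 0.112). Among the alternative settings this list was called only without WT_22mo replicate 2. Its members with the smallest p included Loxl1 (1.16 ± 0.55), which crosslinks elastin, and Plod2 (0.87 ± 0.49), a collagen lysyl hydroxylase. Of 31 matrix glycoproteins 18 were above 0 (median 0.19, camera, adjusted p = 0.339), among them Spp1, the secreted phosphoprotein osteopontin, at 1.41 ± 0.54, and Fbln1 at 1.26 ± 0.64. Fibrillar collagens had a median of 0.59 over 10 members (camera, adjusted p = 0.760), and basement membrane genes 0.29 over 22 (camera, adjusted p = 0.386). Proteoglycans had 8 of 17 members above 0, with a median of -0.06 and a mean of -0.20 (camera, downward, adjusted p = 0.760). Integrins had 9 of 20 above 0 and a median of -0.16, while the test's direction was upward (camera, adjusted p = 0.760). Skeletal muscle genes had 3 of 6 members with an unadjusted p under 0.05, all higher, such as Ttn at 4.71 ± 1.65, and EDA_22mo replicate 1 held 32.7 CPM of Ttn against at most 1.26 CPM in the controls of that age (camera, adjusted p = 0.0919).

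Inflammatory signalling lists were not called at 22 months. TLR4 and NF-kappaB signalling had a median of 0.15 over 28 members (camera, adjusted p = 0.760). It held members on both sides: Ticam1, the adaptor TRIF used by TLR3 and TLR4, at -2.48 ± 0.73, and Ikbkb, a kinase that activates NF-kappaB, at 1.04 ± 0.47. TGF-beta signalling had a median of -0.07 and a mean of 0.12 over 27 members (camera, upward, adjusted p = 0.760), so median and test differed in sign. Complement genes had a median of -0.29 over 20 members and cytokines and chemokines 0.05 over 20 members (camera, adjusted p = 0.760 for each), the latter with a mean of -0.54. MHC class II genes leaned upward, with 5 of 8 members above 0 and a median of 0.55 (camera, adjusted p = 0.202). MHC class I genes had 4 of 18 above 0 and a median of -0.21 (camera, adjusted p = 0.395). Disease-associated microglia genes had a median of -0.03 over 23 members, with an upward test direction (camera, adjusted p = 0.339). Of these, 4 were higher and 1 lower at an unadjusted p under 0.05.

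Among single genes at 22 months, the smallest unadjusted p-values upward belonged to Cped1 (1.35 ± 0.42), Cdkn1a (1.37 ± 0.43), which encodes the cell cycle inhibitor p21, Csrnp2 (1.38 ± 0.44), Evpl (1.59 ± 0.51) and Dym (1.43 ± 0.46). Downward they belonged to the pseudogene Alms1-ps2 (-2.15 ± 0.61), Ticam1, Diablo (-1.89 ± 0.58), a mitochondrial protein that promotes apoptosis, the adhesion molecule Ncam2 (-2.06 ± 0.65) and the kinase Prkd1 (-2.13 ± 0.68). Alms1-ps2 is uncertain, since reads of a pseudogene can be divided with its parent gene, and Alms1 was at -0.09 ± 0.31. None of these passed: edgeR called 0 of 15118 genes, with 599 at an unadjusted p under 0.05 against 756 by chance and a lowest adjusted p of 1. DESeq2 called 47 genes, 10 higher and 37 lower, and limma voom with quality weights called 1, Mesp2, named because the count was small.

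Of the focal genes at 22 months, Fn1 was at -0.76 ± 0.67, Tlr4 at -0.44 ± 0.80, Tgfb2 at -0.08 ± 0.35, Col1a1 at 1.25 ± 1.20, Col3a1 at 0.50 ± 0.70, Col4a1 at 0.32 ± 0.45 and Gfap at 0.20 ± 0.38. The complement genes C3 and C1qa were at 0.75 ± 0.61 and -0.38 ± 0.63, and the myeloid marker Cd68 at 0.34 ± 0.77. Tgfb1, Tgfb3 and Aif1, which were low in some groups, were at 1.89 ± 1.20, -1.49 ± 1.12 and 1.61 ± 1.79. Each of these differences was within 2 standard errors. In simulated data of this size, 28% of genes altered 4-fold and 62% of those altered 8-fold were found. Differences of 4-fold or less were thus mostly not detectable. Genes with a mean under 2 log2 CPM, such as Tgfb1 and Aif1, were not among those altered there.

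At 12 months, myelin genes were higher in EDA-labelled libraries. All 19 tested members lay above 0, with a median of 1.15 (camera, adjusted p = 0.0227, and adjusted p = 0.883 with an estimated correlation). Members with the smallest p were Mal (1.33 ± 0.53), Ppp1r14a (2.13 ± 1.12), Mag (2.46 ± 1.30), an adhesion protein of the inner myelin layer, and Ugt8a (1.95 ± 1.35), which makes the myelin lipid galactosylceramide. Adjusted over the list alone, 0 members passed. Libraries of a group differed widely: the myelin score was 0.70 ± 1.74 against -0.49 ± 2.11 (SD, n = 5 each), with an exact permutation p of 0.341. The call ended in several settings, mostly with a median of similar size. Against a median of voom values of 1.30 with all libraries, it was 0.88 without EDA_12mo replicate 3 (camera, adjusted p = 0.527), 1.41 without EDA_12mo replicate 5 (0.0760), 1.21 without WT_12mo replicate 4 (0.348) and 0.95 without WT_12mo replicate 5 (0.310). It was 1.07 with a covariate for Xist against Y-linked genes (camera, adjusted p = 0.184), 1.15 with one for the share of ENSMUSG00000119584 (0.343) and 0.57 with quality weights (0.243).

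Cytosolic ribosomal protein genes were lower at 12 months, with 17 of 61 members above 0 and a median of -0.46 (camera, adjusted p = 0.0227, and adjusted p = 0.883 with an estimated correlation). Adjusted over the list alone, 0 members passed, and the member with the smallest p, Rps20 at 4.66 ± 2.23, was higher. Rpl6 was at -0.95 ± 0.49, Rpl9 at -1.34 ± 0.82 and Rpl37 at -2.35 ± 1.44. Only 9 members had a median of at least 20 CPM over the libraries other than EDA_12mo replicate 4, so the list rests mostly on genes below that level. The list score of EDA_12mo replicate 4 was -1.74, against -0.13 to 0.33 in the other EDA-labelled libraries of that age, and without that library the median of voom values went from -0.54 to 0.05 and the call ended (camera, adjusted p = 0.257). The median was also above 0 with the share of ENSMUSG00000119584 as a covariate (0.22, camera, adjusted p = 0.680). It was 0.06 without EDA_12mo replicate 4 and EDA_22mo replicate 3 (camera, adjusted p = 0.309). In these settings the test's direction stayed downward. The call ended with a median near the first value without EDA_12mo replicate 5 (-0.59, camera, adjusted p = 0.0760), without WT_12mo replicate 2 (-0.45, 0.149), with a covariate for Xist against Y-linked genes (-0.48, 0.0576) and with a mean of at least 2 log2 CPM (-0.65, 0.248). It ended with a smaller one without WT_12mo replicate 5 (-0.27, camera, adjusted p = 0.0588) and with quality weights (-0.06, 0.282).

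Fibrillar collagens at 12 months had 8 of 10 members above 0 and a median of 1.10 without passing (camera, adjusted p = 0.177). Col5a1 was at 0.69 ± 0.41, and Col5a3 and Col27a1 at 3.68 ± 2.04 and 2.36 ± 1.81. Genes of reactive astrocytes had 18 of 26 members above 0 and a median of 0.59 (camera, adjusted p = 0.30), with the transcription factor Sox9 at 0.75 ± 0.34, the oncostatin M receptor Osmr at 0.53 ± 0.24 and S1pr3 at -0.61 ± 0.23. Complement genes had a median of 0.20 over 20 members (camera, adjusted p = 0.466), with C1qa at 1.44 ± 0.55, C1qb at 1.35 ± 0.62 and C2 at 1.14 ± 0.50. Microglial genes, which include C1qa and C1qb, had a median of 0.08 over 22 members, with a mean of -0.02 and a test direction below 0 (camera, adjusted p = 0.466). TLR4 and NF-kappaB signalling (median 0.05, adjusted p = 0.732) and TGF-beta signalling (median 0.00, adjusted p = 0.826) were not called by camera. Damage-associated ligands had a median of 0.29 over 21 members (camera, adjusted p = 0.466), led by the chaperones Hspa5 (0.75 ± 0.26) and Hsp90aa1 (0.75 ± 0.31).

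The smallest unadjusted p-values upward at 12 months belonged to Actn1 (1.43 ± 0.24), which crosslinks actin filaments at adhesions, Ahsa1 (1.82 ± 0.46), a co-chaperone of HSP90, Sytl2 (1.18 ± 0.31), the focal adhesion protein Zyx (1.38 ± 0.37) and the scaffold Akap12 (1.27 ± 0.34). Downward they belonged to Khk (-2.09 ± 0.59), the fructose kinase, the transcription factor Zic1 (-1.01 ± 0.30), Alms1-ps2 (-1.67 ± 0.49), Csnk2a2 (-0.97 ± 0.31) and Pmp22 (-1.03 ± 0.33), a myelin protein of peripheral nerve. Actn1 stood at 7.26 ± 0.26 log2 CPM in EDA-labelled and 5.84 ± 0.21 in control-labelled libraries (SD, n = 5 each). edgeR called 0 genes, with 689 at an unadjusted p under 0.05 against 756 by chance, and the lowest adjusted p, 0.0936, was that of Actn1. DESeq2 called 32 genes, 25 higher and 7 lower, Actn1 among them, and limma voom with quality weights called 2, Actn1 and Senp3. Without EDA_12mo replicate 4 edgeR called 1 gene, Actn1 (adjusted p = 0.0425). Without any other single library of that age it called 0 genes, with a lowest adjusted p of 0.169 to 0.591. With only the libraries of that age in the fit, edgeR called 0 genes and the lowest adjusted p was 0.998.

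**Figure D3:**
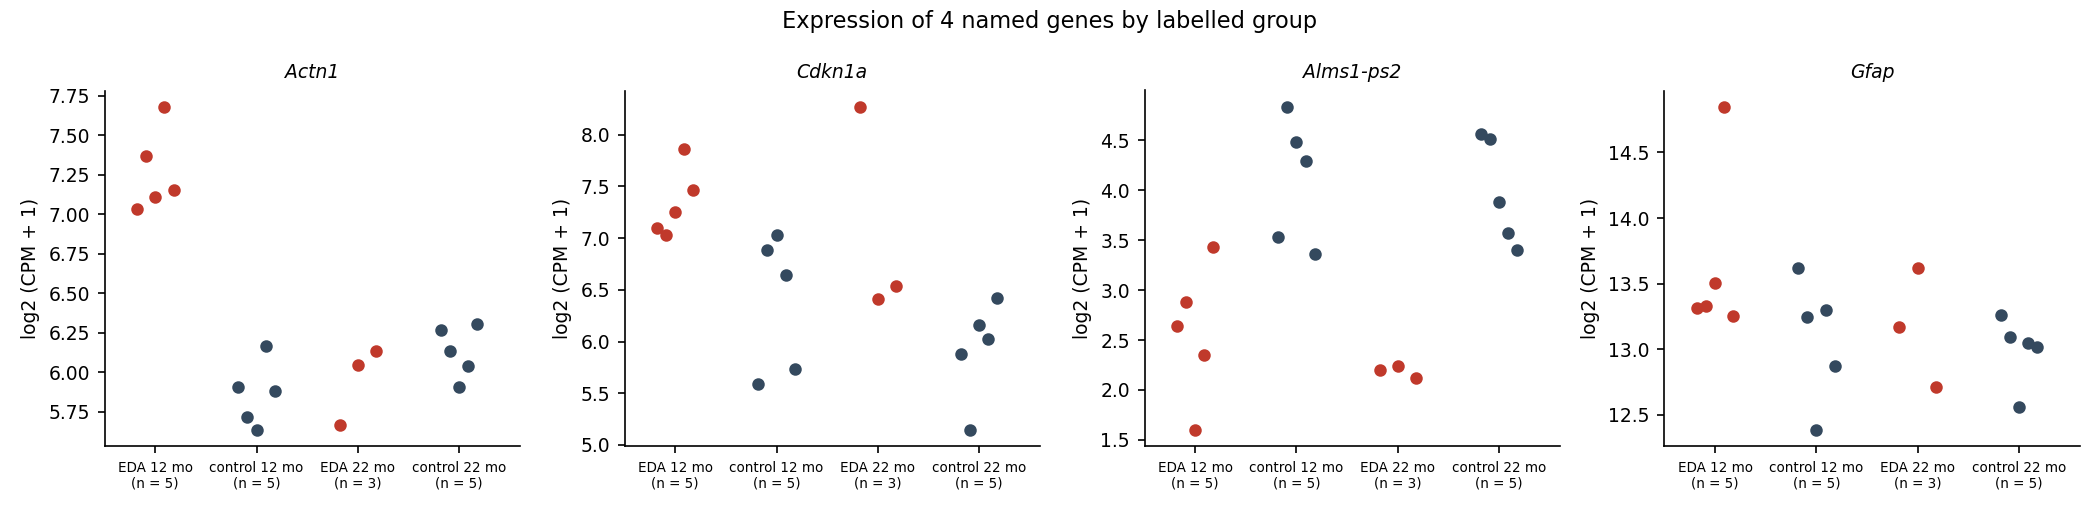
Expression of Actn1, Cdkn1a, Alms1-ps2 and Gfap as log2 of CPM + 1 (vertical axes) by labelled group. Each dot is a library. Actn1 averaged 7.26 log2 CPM in the EDA-labelled libraries at 12 months and 5.93, 5.84 and 6.11 in the EDA-labelled at 22 months and the controls at 12 and 22 months.

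Of the focal genes at 12 months, C1qa had the smallest unadjusted p, 0.0167, and did not pass adjustment in edgeR. Gfap was at 0.66 ± 0.34, Fn1 at -0.31 ± 0.56, Tlr4 at 0.31 ± 0.68, Tgfb1 at 0.76 ± 1.06, Tgfb2 at 0.07 ± 0.30, Tgfb3 at -0.19 ± 0.91 and Col1a1 at 1.28 ± 1.07. Col3a1 was at 0.54 ± 0.62, Col4a1 at 0.58 ± 0.40, C3 at 0.65 ± 0.54, Cd68 at -0.22 ± 0.67 and Aif1 at -2.71 ± 1.69. For Tlr4, Tgfb2 and Tgfb3 the fitted sign and the group means of log2 CPM disagreed, so neither sign is relied on: the means were 3.56 ± 2.63 in EDA-labelled and 3.95 ± 1.11 in control-labelled libraries for Tlr4, 8.23 ± 0.74 and 8.27 ± 0.30 for Tgfb2, and 3.17 ± 0.57 and 2.68 ± 2.12 for Tgfb3 (SD, n = 5 each). The share of reads on Gfap was 3.46% in EDA_12mo replicate 4 and 1.06% to 1.2% in the other 4.

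Between 12 and 22 months in control-labelled libraries, photoreceptor transcripts were the leading list without passing (camera, adjusted p = 0.0508, and adjusted p = 0.843 with an estimated correlation). Of 12 members 11 were above 0, and 7 passed when adjusted over the list alone, among them Gnat1, the transducin subunit of rods, Prph2 and Rp1. Gnat1 lay at 733 CPM in WT_22mo replicate 2 and at 0.371 to 2.05 CPM in the other 4 control-labelled libraries of 22 months. The list score was 5.99 in WT_22mo replicate 2 and -1.17 to 0.07 in the other controls of that age. It was -1.42 to 0.03 in controls of 12 months, so the higher score came mainly from WT_22mo replicate 2. Whether the 7 members pass without that library was not tested. Interferon response genes had 31 of 35 members above 0 and a median of 0.68 (camera, adjusted p = 0.170), complement genes 15 of 20 and a median of 0.44 (adjusted p = 0.170), and myelin genes 19 of 19 and a median of 0.87 (adjusted p = 0.170).

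Single genes with the smallest unadjusted p upward with age in controls were Arl14ep (1.86 ± 0.55), Pip5k1a (2.21 ± 0.73), Atp9a (1.25 ± 0.41) and Raver1 (1.36 ± 0.45). Downward they were the ubiquitin ligase Mid1 (-1.32 ± 0.41), Ammecr1l (-0.89 ± 0.29), Caskin2 (-1.38 ± 0.48), Six4 (-1.66 ± 0.58) and Zfp384 (-1.11 ± 0.39). edgeR called 0 genes, with 530 at an unadjusted p under 0.05 against 756 by chance. DESeq2 called 31, 18 higher and 13 lower, and limma voom with quality weights called 0.

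Between 12 and 22 months in EDA-labelled libraries, interferon response genes were higher at 22 months. Of 35 members 27 were above 0, with a median of 1.41 (camera, adjusted p = 0.00694, and adjusted p = 0.749 with an estimated correlation). They included Iigp1 (3.82 ± 1.07) and Gbp7 (1.97 ± 0.91), interferon-induced GTPases, and the transcription factor Irf1 (1.82 ± 0.80). Adjusted over the list alone, 0 members passed. Iigp1 lay at 180 CPM in EDA_22mo replicate 1 and at 15.5 and 16 CPM in the other 2, and without replicate 1 the median of voom values went from 1.18 to 0.09 and the call ended (camera, adjusted p = 0.597). The exact permutation p of the interferon score was 0.429.

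Single genes with the smallest unadjusted p upward with age in EDA-labelled libraries were the small heat shock protein gene Hspb6 (2.25 ± 0.57), the mineralocorticoid receptor Nr3c2 (1.30 ± 0.34), the cationic amino acid transporter Slc7a2 (1.26 ± 0.34), Zic1 (1.21 ± 0.33) and the desaturase Scd1 (1.78 ± 0.49). Downward they were Actn1 (-1.34 ± 0.28), Mid1 (-2.10 ± 0.51), Rasgef1c (-2.11 ± 0.52), the AP-1 factor Fosl2 (-2.31 ± 0.57) and Kctd3 (-1.48 ± 0.39). edgeR called 0 genes, with 753 at an unadjusted p under 0.05 against 756 by chance and a lowest adjusted p of 0.961. DESeq2 called 51, 7 higher and 44 lower, Actn1 among them, and limma voom with quality weights called 0.

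The interaction of genotype and age asked whether the genotype difference at 22 months departed from that at 12 months. Mitochondrially encoded genes had a lower difference at 22 months in 12 of 12 members (median -0.94, camera, adjusted p = 0.00938, and adjusted p = 0.674 with an estimated correlation). Myelin genes had a lower difference in 19 of 19 members (median -2.66, camera, adjusted p = 0.00938, and adjusted p = 0.853 with an estimated correlation). At 22 months alone the myelin list was not called, with 1 of 19 members above 0 and a median of -1.49 (camera, adjusted p = 0.339, and adjusted p = 0.883 with an estimated correlation). For both lists 0 members passed adjusted over the list alone. Ugt8a lay at 0, 1.10 and 0 CPM in the 3 EDA-labelled libraries of 22 months and at 128 CPM in WT_22mo replicate 3 and EDA_12mo replicate 3. Against a mitochondrial median of voom values of -0.97 the call ended at -0.70 without EDA_22mo replicate 1 (camera, adjusted p = 0.155), -1.08 without EDA_22mo replicate 2 (0.0694), -0.88 without EDA_12mo replicate 1 (0.0848) and -0.84 without WT_12mo replicate 4 (0.143). Against a myelin median of -1.98 it ended at -1.19 without EDA_22mo replicate 2 (camera, adjusted p = 0.255), -1.09 without WT_22mo replicate 3 (0.183), -1.22 without EDA_12mo replicate 3 (0.221), -1.24 without WT_12mo replicate 4 (0.185), -1.35 without WT_12mo replicate 5 (0.195) and -1.20 with quality weights (0.0758).

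Genes with the smallest unadjusted p in the interaction were, upward, Nat8f4 (1.39 ± 0.44), Rassf1 (1.46 ± 0.50), Slc7a2 (1.30 ± 0.46), Clpb (2.02 ± 0.72) and Hspb6 (2.10 ± 0.76). Downward they were Actn1 (-1.61 ± 0.36), Pvr (-2.07 ± 0.58), Mdm4 (-2.38 ± 0.71), an inhibitor of p53, Ugt8a and Cmah, the last at 0 to 3.58 CPM in the EDA-labelled libraries of 22 months and 7.36 to 23 CPM at 12 months. edgeR called 0 genes, with 608 at an unadjusted p under 0.05 against 756 by chance. DESeq2 called 41, 8 higher and 33 lower, Actn1 among them, and limma voom with quality weights called 1, Pja1.

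**Figure D4:**
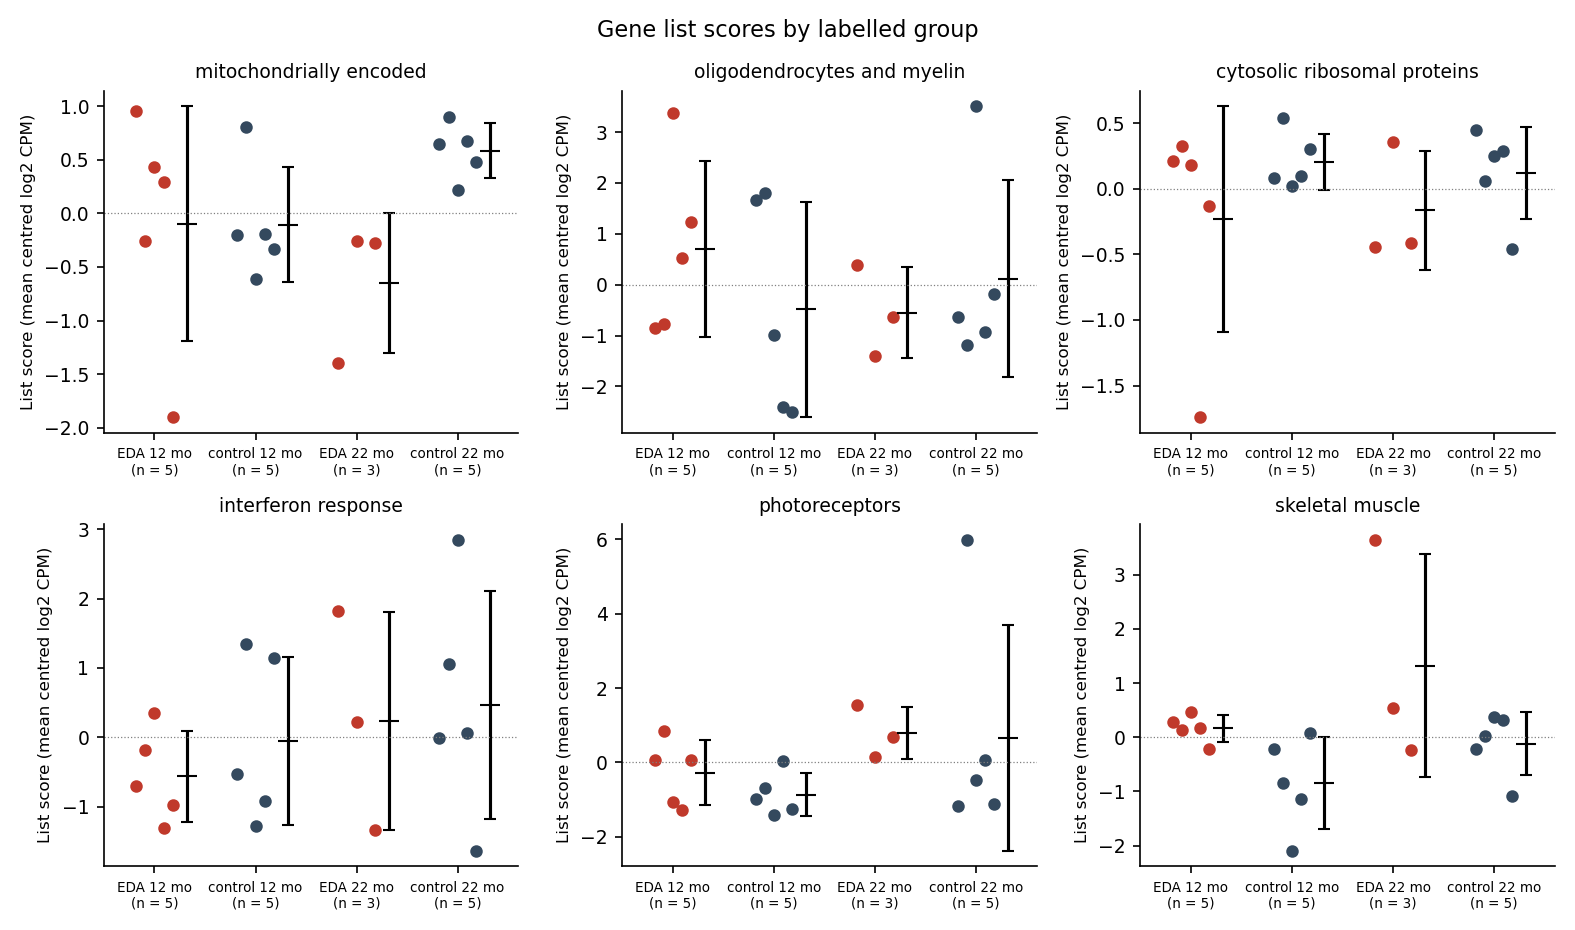
Scores of 6 gene lists by labelled group, as the mean over members of log2 CPM less the gene's mean over all libraries (vertical axes). Each dot is a library, and black marks show the group mean with SD. The 3 EDA-labelled libraries of 22 months have mitochondrial scores of -0.65 ± 0.65 against 0.59 ± 0.25 in the 5 controls, and single libraries reach 5.99 for photoreceptors and 3.51 for myelin.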

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

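The list tests with a covariate for ENSMUSG00000119584 or for Xist against Y-linked genes, the use of left-out libraries to explain the myelin call, with its limit on size, and the tests of GC content, of random sets for transcript length, of ribosomal protein genes in EDA_12mo replicate 4 and of list scores were chosen only after the results they concern were seen. Of 48 groups of library values tested for a library far from its group, 9 held one, where chance alone gives about 1 in 20 groups.

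Mitochondrially encoded transcripts had a median interaction of -0.94, and their score was below the lowest control in all 3 EDA-labelled libraries of 22 months (exact permutation p = 0.036, adjusted p = 0.396 over 44 lists). From 12 to 22 months the score went from -0.10 ± 0.54 to 0.59 ± 0.25 in controls (exact permutation p = 0.040, adjusted p = 0.693). In EDA-labelled libraries it went from -0.10 ± 1.10 to -0.65 ± 0.65 (exact permutation p = 0.393, adjusted p = 0.899). The interaction thus does not lie in the EDA-labelled libraries alone. With the share of ENSMUSG00000119584 as a covariate the median of voom values at 22 months was -0.98 (adjusted p = 6.6e-05 by camera), against -1.09 without it, which argues against that gene's share as the whole cause. With Xist against Y-linked genes as a covariate it was -0.85 (adjusted p = 1.15e-05), which argues in the same way against unequal sexes. Both p-values hold at the preset correlation. With an estimated correlation the call without a covariate was lost (camera, adjusted p = 0.322), and the covariates were not tested so. At 22 months only EDA_22mo replicate 1 had abundant Xist, and its score was -1.40, against -0.26 and -0.28 in replicates 2 and 3. Without replicate 1 the list was still called at the preset correlation (camera, adjusted p = 0.0212), so the size of the difference rests in part on that library. Fragment length has no support and is not excluded: over 18 libraries less group means, the score and the mean fragment length had a Spearman rho of -0.34 (permutation p = 0.166, adjusted p = 0.166 over 2 relations; Pearson r = -0.33, permutation p = 0.184; rho = -0.24 without EDA_22mo replicate 3 and WT_12mo replicate 5). The fragments were 136 ± 34.3 nt in EDA-labelled and 146 ± 12.1 nt in control-labelled libraries of 22 months (SD, n = 3 and 5, exact permutation p = 0.571), and with a negative rho shorter ones go with a higher score, against the pattern; both values are too uncertain to decide. A difference that goes with genotype or age was not tested apart from these and may also underlie the pattern, and the splits by gene lists below do not exclude chance.

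Myelin transcripts had a median interaction of -2.66. They were called higher in EDA-labelled libraries at 12 months (camera, adjusted p = 0.0227, and adjusted p = 0.883 with an estimated correlation). At 22 months they were not called (camera, adjusted p = 0.339), with scores of -0.55 ± 0.90 in EDA-labelled and 0.11 ± 1.94 in control-labelled libraries (SD, n = 3 and 5, exact permutation p = 0.857). The amount of myelinated nerve in the captured section is a candidate explanation: over 18 libraries less group means the myelin score followed that of oligodendrocyte precursors with a Spearman rho of 0.68 (permutation p = 0.003, adjusted p = 0.006 over 2 relations; Pearson r = 0.85, permutation p = 0.0001, and rho = 0.55 without WT_22mo replicate 3 and WT_12mo replicate 1). A single library as the cause cannot be told apart: the call at 12 months ended without any of 4 of the 10 libraries, but the median of voom values was then 0.88 to 1.41 against 1.30, so the lost calls alone do not show that one library made the difference. WT_22mo replicate 3 had a score of 3.51, where the other controls of 22 months lay between -1.19 and -0.18, and without it the control mean at 22 months was -0.74 ± 0.43 (SD, n = 4), so the score difference turned to 0.19, and the median of voom values in the interaction went from -1.98 to -1.09. The relation of the myelin score to the precursor score cannot tell the captured section from the number of oligodendrocyte lineage cells within it. Whether genotype alters myelin apart from the captured tissue was not tested.

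EDA_12mo replicate 4 stood apart from the other libraries. Its median Spearman correlation with them was 0.671, where the others of its group had 0.858 to 0.881, and Lars2 and Gfap took 6.9% and 3.46% of its reads, where the others had 3.16% to 4.13% and 1.06% to 1.2%. Of 1358 genes with a median of at least 100 CPM elsewhere, 209 were over 16-fold lower in it and 0 over 16-fold higher, while no other library had more than 3 lower; Ubb, a ubiquitin gene used by every cell, lay at 15.8 CPM against a median of 8828 CPM. Another mix of cell types as the whole cause is argued against by ribosomal protein genes. Of the 9 with a median of at least 20 CPM, 66.7% were over 16-fold lower, and none were in the other 17 libraries. At the first minimum of 100 CPM, which left only 4 genes, 4 of 4 were. That minimum was lowered because it left so few genes, after the result was seen. These genes cannot show whether another mix added to the loss of other genes, and they were not compared with genes of like length. Transcript length cannot be told apart as a part of the cause: the lower genes had a median length of 3303 nt against 4382 nt, at percentile 29.6 of abundant genes. The limit set beforehand, percentiles 25 to 75, was too wide for a median of 209 genes, since 10000 random sets of as many had medians of 3730 to 5141 nt. Of the shortest 20% of abundant genes 30.3% were lower, and of the longest 20% 5.2%. GC content cannot be told apart either, with 56.0% of the lower genes still so after adjustment for GC, where removal of the overall mean alone left 63.2%. The labels name no difference that sets this library apart from its group, so no explanation by genotype or age was tested.

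The ribosomal protein score of the same library was -1.74, where the other 4 lay between -0.13 and 0.33. EDA_12mo replicate 3 held 18488733 expected counts, where the others of its group held 13518167 to 14426292. WT_12mo replicate 3 had a median Spearman correlation of 0.807 with the other libraries, where the rest of its group had 0.845 to 0.858. WT_12mo replicate 5 held 1485 Fn1 reads, where its group otherwise held 212 to 465. WT_22mo replicate 2 had a photoreceptor score of 5.99, where its group otherwise lay between -1.17 and 0.07.

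Other splits of the same libraries into groups of the same sizes were tested as well. Where the real split called 0, every split calls at least as many by construction, so these counts say nothing about chance. For genes that held in every comparison: 56 of 56 for genotype at 22 months (real 0, highest other 6), 100 of 100 at 12 months (0 and 1), 100 of 100 for age in controls (0 and 1), 56 of 56 for age in EDA-labelled libraries (0 and 3), 100 of 100 for the interaction (0 and 3) and 100 of 100 for genotype over both ages (0 and 4). For gene lists it held for age in controls (100 of 100, 0 and 8). The other list counts were above 0, and at least as many lists were called, the real split included, in 51 of 56 splits at 22 months (real 1, highest other 7), 47 of 100 at 12 months (2 and 7), 45 of 56 for age in EDA-labelled libraries (1 and 7) and 59 of 100 for the interaction (2 and 9), so chance cannot be excluded for these 4. Why some splits called more lists than the real one was not tested; all used the preset correlation of 0.01, where the estimated correlation of called lists was 0.114 to 0.691, and the real split called 0 lists with it. At an unadjusted p under 0.05, splits with at least as many genes as the real one were 28 of 56 at 22 months (real 599, highest other 2100), 8 of 100 at 12 months (689 and 856), 79 of 100 for age in controls (530 and 1132), 10 of 56 for age in EDA-labelled libraries (753 and 1753) and 45 of 100 for the interaction (608 and 1855), so these counts do not exclude chance either.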

How the results depend on the processing

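Added after seeing the data were the tests with a covariate for ENSMUSG00000119584 or detected genes, those without both EDA_12mo replicate 4 and EDA_22mo replicate 3, and quality weights and the Xist covariate in list tests. No paired analysis was possible because the labels give no shared replicate numbers. edgeR called 0 genes in all 5 comparisons with DESeq2 size factors, without a filter, with only the compared groups (not run for the interaction), and with the photoreceptor, myelin, Xist, ENSMUSG00000119584 or detected-genes covariate. DESeq2's own test called 47 and 32 genes between genotypes at 22 and 12 months, 31 and 51 with age in control- and EDA-labelled libraries, and 41 in the interaction; the cause was not tested. Voom with quality weights called 1, 2 and 1 in the 22-month, 12-month and interaction comparisons. At 12 months 1 gene, Actn1, was called with a mean of at least 2 log2 CPM (fewer genes tested), with the first surrogate variable and without both libraries. The adjusted p of Actn1 was 0.0473, 0.0397 and 0.0236 in edgeR. With only the compared groups in the fit, the lowest adjusted p over all genes at 12 months was 0.998. Leaving out each library gave 0 to 1 genes at 12 months (1 without EDA_12mo replicate 4) and 0 to 0 elsewhere.

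Called lists at 22 months numbered 1, and 0 with an estimated correlation, 2 with quality weights, 2 with the myelin and 2 with the Xist covariate, 5 with the ENSMUSG00000119584 covariate and 3 without both libraries. At 12 months they numbered 2, and 0 with an estimated correlation, 1 with the higher filter, 1 with quality weights, 0 with the Xist and 0 with the ENSMUSG00000119584 covariate, 1 without both libraries, and 3 with the myelin and 3 with the detected-genes covariate. Interferon response genes, not called otherwise (adjusted p = 0.177), were called lower at 12 months with quality weights, with these last 2 covariates and without WT_12mo replicate 3 or 4. With age in controls they numbered 0, and 1 with the higher filter, 1 with the photoreceptor, 1 with the myelin and 1 with the detected-genes covariate, and 3 with the Xist covariate. With age in EDA-labelled libraries they numbered 1, and 0 with an estimated correlation, 4 with the higher filter, 7 with quality weights, 3 with the myelin, 4 with the ENSMUSG00000119584 and 5 with the detected-genes covariate, and 10 without both libraries. In the interaction they numbered 2, and 0 with an estimated correlation, 5 with quality weights, 7 with the detected-genes covariate and 8 without both libraries. For the 6 list calls the estimated correlation was 0.114 to 0.691, above the preset 0.01, which widens the test; for the other settings the cause was not tested. Leaving out each library gave 1 to 5 lists (5 without WT_22mo replicate 2), 0 to 3, 0 to 4, 1 to 7 and 0 to 6, in the order above. Mitochondrially encoded genes at 22 months kept their call in every one of these settings but the estimated correlation (adjusted p = 0.322). Without EDA_22mo replicate 1 their adjusted p was 0.0212, against 6.24e-07 with all libraries (camera).

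Medians of voom values differ from edgeR's, as for the myelin list in the interaction, at -1.98 against -2.66. The myelin list went from 1.30 to 0.17 at 12 months and from -1.98 to 0.28 in the interaction with the myelin score as a covariate, with the test's direction turned, because the covariate is made from these genes. The ribosomal list at 12 months went from -0.54 to 0.22 with the ENSMUSG00000119584 covariate and to 0.06 without both libraries, while the test's direction stayed downward. The EDA exon share difference stayed below 0 at 22 months, at -48 to -23 percentage points without each library, and ran from -17.2 to 7.9 at 12 months, the last without WT_12mo replicate 5. Of 26 pairs of focal gene and comparison 11 changed sign under a setting. Genes named by rank were selected for small p and separated libraries, so their signs are no test of stability; 22 values of single genes passed the threshold under a setting where they otherwise did not. In simulated data, 4-fold differences in single genes were found at 28% for 3 against 5 libraries and 36% for 5 against 5. The rates for 8-fold differences were 62% and 74%. Differences of 4-fold or less were thus mostly below what 3 or 5 libraries of this spread detect.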

Other observations

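All tests of list scores and of genotype over both ages below were chosen only after the results were seen; the test of genes near Fn1 was set before its result.

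Of 44 list scores, 4 had an exact permutation p under 0.05 between labels at 22 months against 1.57 by chance, 3 at 12 months against 2.10, 2 with age in controls against 2.10 and 0 with age in EDA-labelled libraries against 1.57, and none passed adjustment. With 3 against 5 libraries the smallest possible exact p is 0.036. Adjusted over 44 lists, it could pass only if most lists reached it at once, so not passing there says little. At 22 months heat shock genes scored -0.35 ± 0.14 in the 3 EDA-labelled and 0.15 ± 0.19 in the 5 control-labelled libraries (exact permutation p = 0.036, adjusted p = 0.396), with all 3 below the lowest control; the co-chaperone Dnajb1 was at -2.02 ± 0.80 and Hspa8 at -0.85 ± 0.43. Matrix remodelling enzymes scored 0.31 ± 0.06 against -0.15 ± 0.28, and pericyte and smooth muscle genes 0.38 ± 0.06 against -0.11 ± 0.30, each with all 3 above the highest control (exact permutation p = 0.036, adjusted p = 0.396). At 12 months fibrillar collagens scored 0.58 ± 0.38 against -0.54 ± 0.70 (exact permutation p = 0.040, adjusted p = 0.579), genes of the unfolded protein response 0.33 ± 0.28 against -0.09 ± 0.29 (exact permutation p = 0.048, adjusted p = 0.579), and skeletal muscle genes 0.17 ± 0.25 against -0.84 ± 0.85 (exact permutation p = 0.024, adjusted p = 0.579). With age in controls, senescence genes scored -0.31 ± 0.36 at 22 months against 0.15 ± 0.14 at 12 months (exact permutation p = 0.032, adjusted p = 0.693), and mitochondrially encoded genes 0.59 ± 0.25 against -0.10 ± 0.54 (exact permutation p = 0.040, adjusted p = 0.693).

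Over both ages edgeR called 0 genes between genotype labels, with 720 at an unadjusted p under 0.05 against 756 by chance and a lowest adjusted p of 1.00. The smallest unadjusted p, 9.88e-05, was that of Alms1-ps2, at -1.91 ± 0.40, which lay below the lowest control in 7 of 8 EDA-labelled libraries; as a pseudogene it is uncertain. Diablo was at -1.44 ± 0.37 and below the lowest control in 7 of 8. The transcriptional repressor Bach2 was at 1.21 ± 0.29 and above the highest control in 6 of 8, and Bach2os, whose reads cannot be separated from those of Bach2 without strand, at 1.86 ± 0.51 and above it in 8 of 8. Cdkn1a was at 1.13 ± 0.29 and above the highest control in 6 of 8. Across 7597 genes, which are not independent replicates, the genotype differences at 22 and 12 months had a Spearman rho of 0.08, and the age differences in the 2 genotypes 0.07.

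A hypothesis was that sequence flanking Fn1, carried along with the EDA allele, could alter nearby genes. The 96 tested genes within 10 Mb of Fn1 had a mean size of the signed root of the F statistic of 0.742, against a median of 0.809 over 12949 windows elsewhere, at percentile 16.3. Of them 2 had an unadjusted p under 0.05, and edgeR called 0. The test argues against a broad effect across these genes that stands out from other windows. An effect on a few of them could be lost in the mean and is not excluded.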
